A study of Mus musculus with 6 samples.

How the data were processed

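The series holds 6 RNA-seq libraries of mouse small intestine at postnatal day 14, 3 labelled wild type and 3 labelled Erk1/2 knockout, and each library's file was assigned to its group by the sample title. Per the labels' protocols, tissue was frozen, RNA was extracted with Trizol, and polyA libraries were made from total RNA with the Illumina TruSeq RNA kit. The submitters' processing notes name TopHat2 2.1.0, HTSeq 0.6.0 and DESeq2 without a version, and the genome build mm10, without their order. The gene annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here, so antisense, overlapping and near-identical genes could share reads.

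The deposited values are a score per gene symbol, whole numbers that are not raw counts. The submitters' processing notes name DESeq2, and the values bear the marks of counts divided by a factor per library and rounded: recomputed median-ratio factors were nearly equal in all 6 files although totals differed, and regular whole numbers were missing or doubled at the low end. In wild type 3, labelled knockout 1 and labelled knockout 3, 7, 10 and 2 of the low whole numbers occurred in no gene. They are called normalised counts here. The factors were estimated from those gaps as 1.1773, 1.1189 and 0.8902 for wild type 1 to 3 and 0.8412, 1.092 and 0.9682 for labelled knockout 1 to 3, which puts the reads at 16184967, 15263439 and 12547273 and at 14429583, 16301250 and 14354383. On 6 simulated libraries the largest error of an estimated factor was 0.001. Single reads could not be recovered for all libraries because of the rounding, so counting intervals were not computed.

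Each file holds the same 24452 symbols, and no column was left unused. Of these symbols, 27 had been turned into dates and 5079 were at 0 in all libraries. Mitochondrially encoded genes are not analysed here, and the haemoglobin genes checked were at 0. Coordinates were taken by symbol from the GENCODE vM21 annotation of GRCm38, the assembly that mm10 names, and all 32 entries of named genes had a match.

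The design fixed before the data were examined was a quasi-likelihood count model with trimmed-mean scaling. Since the values are not counts, that model was not used, and limma 3.58.1 in R 4.3.3 was run instead on log2(normalised count + 1), with an intensity trend in the prior variance, on genes with at least 10 in at least 3 libraries (14686 genes). The authors' scaling was kept. The pseudocount of 1 and the filter were set after the unit was found and before any test was run. Fold changes are on this log2 scale and understate the change of low genes. Tests were two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05, with 4 residual and 2.99 prior degrees of freedom. Genotype was the only term.

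Before the data were examined, 46 gene lists were fixed from textbook knowledge: ERK signalling and its feedback, EGF ligands, Wnt, Notch and stem cell genes, proliferation, intestinal epithelial cell types and functions, suckling and weaned enterocytes, metabolism, stress, immune responses, and markers of other cell types including blood, pancreas, fat, muscle, vessels and nerve. Of these, 41 had at least 5 tested members and entered camera with a preset correlation of 0.01, adjusted over those lists. Of the 41, 17 were called, 10 higher and 7 lower, none with an estimated correlation, where the lowest adjusted p was 0.229, and fry, which asks whether a list's genes move on balance one way, called 13, of which 12 were among the 17. Member counts are given over all genes tested and adjusted over the list alone.

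The rule for named genes was also set then. It included Mapk3, and took the 10 largest rises and 10 largest falls among called genes with the genotypes apart and a mean of at least 5 CPM, leaving out unnamed gene models and antigen receptor segments. It further took the 5 most abundant called genes in each direction, up to 4 members of each list by p-value, and 2 abundant members of lists without a call. Genes that the rule picked, and members of uncalled lists, are named only in part. Genes named to describe the libraries (Ddx3y, Xist and Fabp6) were chosen after their values were seen.

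The alternatives changed scaling, filter, test, threshold, replicate block, list test and the libraries used, and each library was left out in turn. Alternatives added after seeing the data were the trimmed-mean scaling in an own implementation, pseudocounts of 0.5 and 5, limma-voom on values times the estimated factors, a segment score or sex as a covariate, and leaving out both libraries with low segment scores. The scripts were tested on simulated data with the means, spreads and scaling factors of these libraries: of genes changed 1.5-fold, 2-fold and 4-fold, 0 of 67, 12 of 66 and 46 of 64 were called among 14509 genes, with 2 unchanged genes called. Far fewer genes were changed in the simulation than were called here, so these rates do not carry over to the libraries. Replicate libraries differed by a chi-square of at least 19.4 per degree of freedom, so none was counted as a duplicate. Figures were drawn with matplotlib 3.10.9.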

Results

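Gene expression in the small intestine of C57BL/6 mice was measured by RNA-seq at postnatal day 14, an age at which mice still suckle. There were 3 libraries labelled wild type and 3 labelled Erk1/2 knockout, with a homozygous loss of ERK kinases that includes ERK1, encoded by Mapk3. The series title sets the question as the part these kinases play, through negative feedback, in the development and upkeep of the intestine after birth. The comparison of the genotypes was the only one the labels gave. Values were normalised counts for 24452 gene symbols. They summed to 13746946, 13641468 and 14094100 in wild type 1 to 3 and to 17153570, 14927201 and 14825845 in labelled knockout 1 to 3. The reads behind them were estimated at between 12547273 and 16301250 per library. The labels describe triplicates without saying that each came from a separate animal, so p-values measure the spread between these 6 libraries.

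Mapk3 was not lower in the libraries labelled knockout. The gene (ERK1; chromosome 7, 126759601 to 126765819, plus strand, GRCm38) had normalised counts of 3142, 2788 and 2004 in wild type 1 to 3 and of 3363, 2280 and 2734 in labelled knockout 1 to 3. The means were 2645 ± 582 and 2792 ± 544 (SD, n = 3 each), a log2 fold change of 0.09 ± 0.22 (SE) with a limma adjusted p of 0.819. Its sign was negative under scaling by library totals, at -0.089. This is a total over the whole gene and holds no values for single exons. The Mapk3 transcripts therefore do not bear out the genotype labels, and every direction given here is that of the libraries labelled knockout against those labelled wild type.

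The libraries labelled knockout had far more transcripts of secreted antimicrobial lectins and other epithelial defence genes. They had more of many enzymes of cholesterol synthesis and glycolysis, and less of lactase and of several B cell genes. Camera called the antimicrobial, cholesterol, glycolysis and B cell lists with a preset correlation. None was called with an estimated correlation (camera adjusted p of 0.229, 0.229, 0.262 and 0.373). Reg3b, a lectin that the gut epithelium secretes against bacteria, rose from 360 ± 436 to 120168 ± 48442 normalised counts (SD, n = 3 each). Its log2 fold change was 9.27 ± 1.03, and it was the most abundant of the genes called higher. In all, 1291 of 14686 genes tested were called at a limma adjusted p under 0.05, 712 higher and 579 lower. Of these, 716 differed by at least 2-fold. All 1291 had the 3 libraries of each genotype apart, as had 37.6% of all genes tested, where chance gives 10%. The higher share of the calls, 55.2%, depended on scaling: it was 44.5% with upper-quartile factors and 29.6% with library totals. Library totals moved the median log2 fold change of all genes from -0.01 to -0.19. None of the called genes that were tested there changed sign under any of these scalings. That was largely fixed, since their median absolute log2 fold change was 1.07, large beside such a shift. In fits that left out 1 library, the median ratio of the called genes' fold changes to those with all libraries ran from 0.958 to 1.04. These fits share all their libraries with the full fit, so a ratio near 1 was largely fixed too. The count of calls moved far more in these smaller fits. It was 78 without wild type 1, 57 without wild type 2 and 387 without wild type 3. It was 2998 without labelled knockout 1, 619 without labelled knockout 2 and 28 without labelled knockout 3. The higher share of these calls was 91.0%, 98.2% and 69.5% without wild type 1, 2 and 3. It was 51.6%, 52.2% and 92.9% without labelled knockout 1, 2 and 3.

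**Figure D1:**
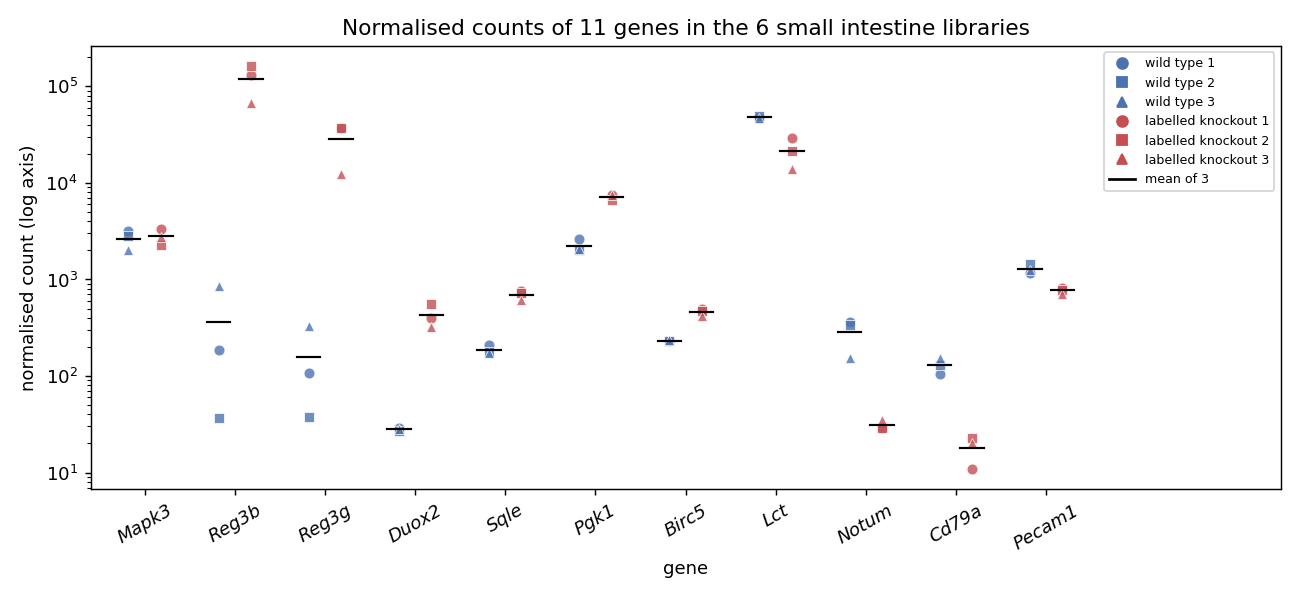
Normalised counts (log axis) of 11 genes in the 3 wild type libraries (blue) and the 3 libraries labelled knockout (red), with symbols for replicates 1 to 3 and bars for the means. Mapk3 overlaps between the genotypes, while Reg3b has 37 to 856 in wild type and 67261 to 162345 in the libraries labelled knockout.

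The 10 largest rises were led by Reg3b and its neighbour Reg3g, another bactericidal lectin, with a log2 fold change of 7.85 ± 0.79 (limma adjusted p = 0.0078). Reg3b lies on chromosome 6 from 78370657 to 78373466 and Reg3g from 78466269 to 78468872. Hp, the haemoglobin-binding acute phase protein haptoglobin, rose by 6.01 ± 0.57 on the log2 scale, and Saa3, a serum amyloid of epithelium and macrophages, by 5.69 ± 0.53. Prss27, a membrane-anchored serine protease, rose by 5.13 ± 0.40. Cpn2, a subunit of carboxypeptidase N, rose by 5.04 ± 0.56, and Duoxa2, which matures the hydrogen peroxide-making oxidase DUOX2, by 4.94 ± 0.61. S100a9, a calprotectin subunit, rose by 4.88 ± 0.59, the orphan receptor gene Gprc5a by 4.36 ± 0.54 and Oit1 by 4.27 ± 0.63. Among the 10 largest falls, Serpina1a and Serpina1e, near-identical alpha-1-antitrypsin genes whose reads could have been split between copies, changed by -4.81 ± 0.81 and -4.38 ± 0.90. Each of these values alone is uncertain. Alox15, a lipoxygenase, changed by -3.45 ± 0.48 and St3gal5, the synthase of ganglioside GM3, by -3.30 ± 0.42. Notum, a secreted deacylase that inactivates Wnt proteins, changed by -3.06 ± 0.34. Pbld1 changed by -2.91 ± 0.62, the basement membrane collagen gene Col4a3 by -2.90 ± 0.25 and the B cell receptor component Cd79a by -2.82 ± 0.32. Tmie changed by -2.54 ± 0.52 and Lrat, which esterifies retinol, by -2.48 ± 0.32. All 20 passed at limma adjusted p-values of 0.0391 or less. The number of the 20 still called was 10 without wild type 1, 7 without wild type 2 and 17 without wild type 3. Without a labelled knockout library, Hp, Prss27 and Cpn2 did not pass the filter and were untested. Of the other 17, 17 stayed called without labelled knockout 1, 13 without labelled knockout 2 and 2 without labelled knockout 3. None changed sign where tested, which was fixed by picking genes with the genotypes apart.

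The most abundant genes that rose, besides Reg3b, were the glycolytic enzyme gene Gapdh (log2 fold change 1.47 ± 0.21) and the epithelial keratin gene Krt8 (1.28 ± 0.20). They were followed by Lypd8, whose product keeps flagellated bacteria off the epithelium (1.99 ± 0.22), and the actin gene Actg1 (1.12 ± 0.21). The most abundant genes that fell were Lct, encoding lactase (-1.22 ± 0.28, from 48086 ± 1621 to 21486 ± 7504 normalised counts, SD, n = 3 each), and Pck1, the gluconeogenic enzyme (-2.43 ± 0.55). They were joined by Cat, encoding catalase (-0.89 ± 0.21), Asah2, a ceramidase of the brush border (-1.40 ± 0.28), and Chpt1, which completes phosphatidylcholine synthesis (-0.68 ± 0.15). Of these 10 genes, Reg3b included, 0, 1 and 5 stayed called without wild type 1, 2 and 3, and 10, 5 and 0 without labelled knockout 1, 2 and 3.

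The antimicrobial and acute phase list had the largest median of the 17 called gene lists, a log2 fold change of 2.57. Of its 13 members tested, 8 rose and none fell, and 8 rose when adjusted over the list alone (camera adjusted p = 1.55e-06, and adjusted p = 0.229 with an estimated correlation). Besides Reg3b and Reg3g, the members included Duox2, an oxidase of the mucosal surface, with 3.85 ± 0.23, and Retnlb, a bactericidal protein of goblet cells. Retnlb was at 0 in all 3 wild type libraries and averaged 128 in the libraries labelled knockout, at least 42.8-fold higher against a floor of 3 counts per library. In the goblet cell list, 5 of 15 members rose, or 9 adjusted over the list alone (camera adjusted p = 1.70e-05, and adjusted p = 0.373 with an estimated correlation). Spink4, a protease inhibitor of goblet cells, had 2.19 ± 0.34 and Zg16, a mucus lectin, 1.44 ± 0.32. The Paneth cell list had 3 of 13 members higher, 4 adjusted over the list alone, with all 13 fold changes positive (camera adjusted p = 0.000967, and adjusted p = 0.587 with an estimated correlation). Mmp7, the protease that activates defensins, had 3.09 ± 0.56 and Mptx2, a Paneth cell pentraxin, 2.51 ± 0.32. Lyz1, encoding lysozyme, did not pass at 2.21 ± 0.59 (limma adjusted p = 0.0626). Paneth genes did not follow the labels alone: the mean of the list, centred over the libraries, was -1.76, -1.90 and 0.93 in wild type 1 to 3 and 1.73, 0.58 and 0.42 in labelled knockout 1 to 3. The mean log2 fold change of this list was 1.82 with all libraries and 2.74 without wild type 3. That of the goblet list was 1.29, and 0.89 over the 14 members besides Retnlb, which fell to 0.68 without labelled knockout 1, where Retnlb was untested. Of the 8 antimicrobial genes, 5, 5 and 8 stayed called without wild type 1, 2 and 3. Retnlb was untested without a labelled knockout library, and of the other 7, 7, 6 and 2 stayed called without labelled knockout 1, 2 and 3. Of the 5 goblet genes, 1, 1 and 5 stayed called without wild type 1, 2 and 3, and of the 4 besides Retnlb, 4, 2 and 0 without labelled knockout 1, 2 and 3. The 3 Paneth genes gave 0, 0 and 3 and then 2, 1 and 0 in the same order.

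Markers of neutrophils, which could enter the tissue, moved with the antimicrobial genes but not as a whole. S100a9, S100a8 (4.57 ± 0.65) and the lactoferrin gene Ltf (2.13 ± 0.34) rose, and Retnlg fell by 1.51 ± 0.29 on the log2 scale. Thus 3 members rose and 1 fell of 6 tested, or 4 and 1 adjusted over the list alone (camera adjusted p = 0.0158, and adjusted p = 0.584 with an estimated correlation). S100a8, S100a9 and Ltf are also made by epithelium. The call was lost without labelled knockout 1, at a camera adjusted p of 0.162, without labelled knockout 3, both with 5 of the 6 members tested, and without both libraries with low segment scores (wild type 3 and labelled knockout 1), at 0.0759. Among inflammatory cytokines and chemokines, Cxcl2 and Cxcl5, which attract neutrophils, rose by 2.72 ± 0.40 and 2.79 ± 0.45, from mean normalised counts of 6.67 and 9. No other of the 11 members tested passed over all genes, and 2 passed adjusted over the list alone. This list was not called by camera (adjusted p = 0.0916, and adjusted p = 0.399 with an estimated correlation). It was called by fry (adjusted p = 0.0268), in 9 of 13 other camera settings, and without wild type 1 or wild type 2. The fits without wild type 1 or 2 tested 10 of the 11 members. With all libraries the mean log2 fold change of those 10 was 0.970, compared with 0.745 for all 11. Of the 4 neutrophil genes, 0, 0 and 4 stayed called without wild type 1, 2 and 3, and of the 3 besides S100a8, which was untested there, 3, 2 and 0 without labelled knockout 1, 2 and 3. Cxcl2 and Cxcl5 both stayed called without wild type 3, and Cxcl5 without labelled knockout 1, where Cxcl2 was untested.

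Nearly the whole pathway of cholesterol synthesis was higher in the libraries labelled knockout. Of 19 members tested, 15 rose and all 19 passed adjusted over the list alone, with a median log2 fold change of 1.29 (camera adjusted p = 2.27e-15, and adjusted p = 0.229 with an estimated correlation). Sqle, the squalene epoxidase, rose by 1.89 ± 0.15 on the log2 scale (limma adjusted p = 0.00527). Msmo1, a sterol methyl oxidase, rose 4.29-fold, and Idi1, an isoprenoid isomerase, rose 2.85-fold. The genes that stayed called were 6, 6 and 11 of the 15 without wild type 1, 2 and 3 and 15, 11 and 5 without labelled knockout 1, 2 and 3.

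Glycolysis and hypoxia response genes rose as well, 9 of 14 tested with none lower, or 12 higher and 1 lower adjusted over the list alone (camera adjusted p = 1.55e-06, and adjusted p = 0.262 with an estimated correlation). Slc2a1, the glucose transporter GLUT1, rose by 1.93 ± 0.18 and Pgk1, a kinase of glycolysis, by 1.70 ± 0.16. Ldha, which makes lactate, rose by 1.36 ± 0.18 and Aldoa, an aldolase, by 1.29 ± 0.16. In the amino acid stress response list, Asns (1.10 ± 0.16), Psat1 (0.94 ± 0.16) and Shmt2 (0.98 ± 0.17) rose, enzymes that make asparagine, serine and methylene folate. Sesn2, a stress-induced inhibitor of mTORC1, changed by -1.18 ± 0.24. The list of 16 tested had 3 higher and 1 lower, 5 and 1 adjusted over the list alone (camera adjusted p = 0.0478, and adjusted p = 0.343 with an estimated correlation). Its call was lost without wild type 3 and without labelled knockout 1, where the camera adjusted p was 0.202, and without both of these libraries (0.211). It was also lost with the segment score as a covariate (0.112) and with a filter at 1 CPM (0.052). Its 4 genes gave 0, 0 and 1 still called without wild type 1, 2 and 3 and 4, 3 and 0 without labelled knockout 1, 2 and 3. Of the 9 glycolysis and hypoxia genes, 2, 2 and 5 stayed called without wild type 1, 2 and 3 and 9, 7 and 1 without labelled knockout 1, 2 and 3.

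**Figure D2:**
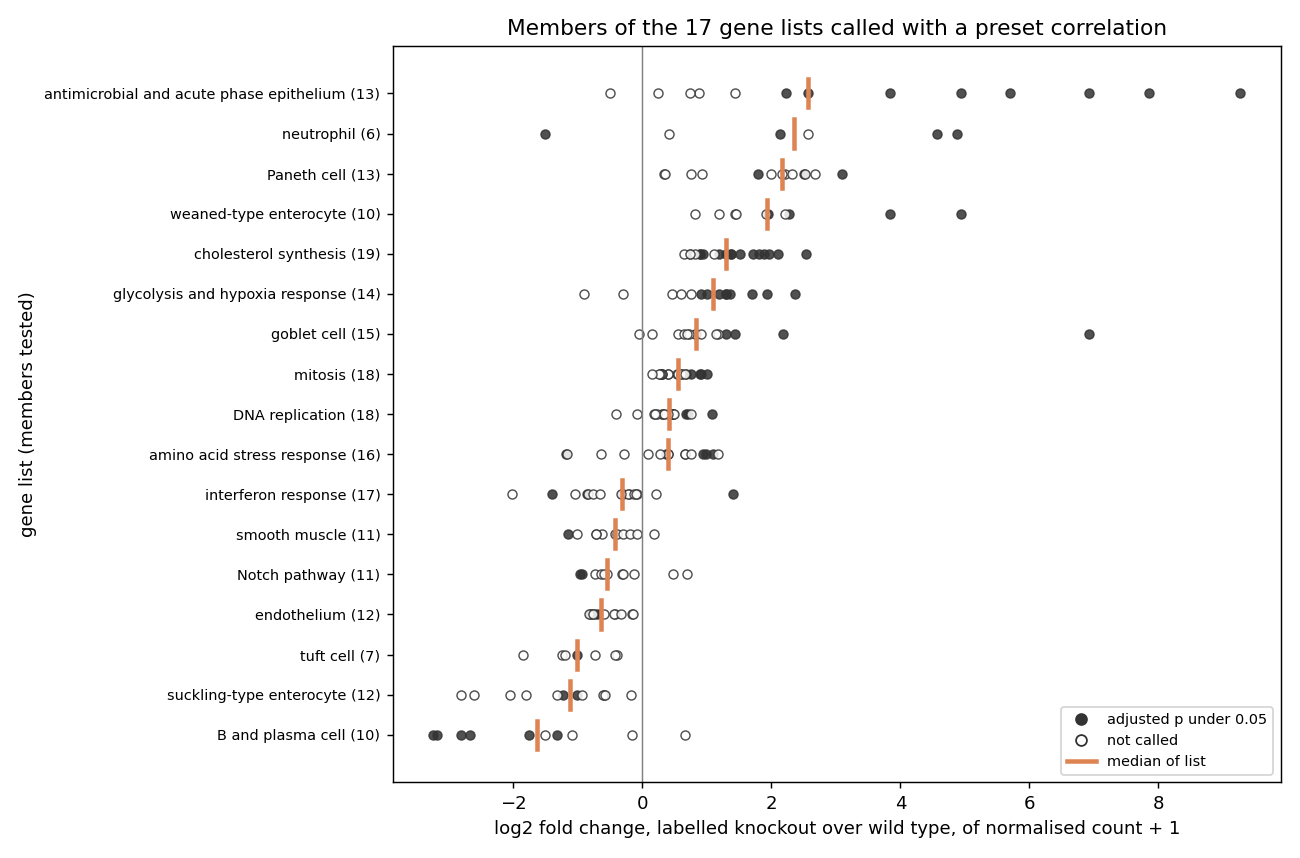
Log2 fold changes (labelled knockout over wild type, on normalised count + 1) of the members of the 17 gene lists called with a preset correlation, filled where the gene passed an adjusted p of 0.05 and with the list median as an orange bar. Medians run from -1.63 for B and plasma cell genes to 2.57 for antimicrobial and acute phase genes, and no list was called with an estimated correlation.

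The list of genes that mark enterocytes after weaning was called higher and that of suckling enterocytes lower. In the weaned-type list 4 of 10 members rose, 6 adjusted over the list alone, and all 10 fold changes were positive (camera adjusted p = 1.55e-05, and adjusted p = 0.262 with an estimated correlation). Krt20, a keratin of mature surface cells, rose by 1.94 ± 0.32, and Fut2, which adds fucose to surface glycans, by 2.27 ± 0.39, beside Duox2 and Duoxa2, which the antimicrobial list also holds. In the suckling-type list Lct and Prdm1, the repressor BLIMP1 of the fetal and suckling epithelium (-1.02 ± 0.21), fell. These were 2 of 12 tested, or 6 adjusted over the list alone, and all 12 fold changes were negative (camera adjusted p = 0.00131, and adjusted p = 0.587 with an estimated correlation). Cubn, an endocytic receptor, did not pass at -2.05 ± 0.52 (limma adjusted p = 0.0563). A segment score, the mean of proximal intestine genes minus that of ileal bile acid genes on the log2 scale, ran opposite to the suckling list. It was 1.21, 0.58 and -3.82 in wild type 1 to 3 and -3.07, 2.52 and 2.57 in labelled knockout 1 to 3. Fabp6, the ileal bile acid binding protein, did not pass the filter and is not in the score. It was at 4 in wild type 3 and at 1947 in labelled knockout 1, so a low score does not give these libraries the same ileal markers. The mean of the suckling list, centred over the libraries, was 0.069, 0.54 and 1.36 in wild type 1 to 3 and 0.61, -1.06 and -1.51 in labelled knockout 1 to 3. Of the 4 called weaned-type genes, 2, 1 and 3 stayed called without wild type 1, 2 and 3 and 4, 2 and 1 without labelled knockout 1, 2 and 3. Lct and Prdm1 stayed called only without labelled knockout 1.

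Both proliferation lists were called higher, while most of their members did not pass over all genes. All 18 mitosis genes had positive fold changes and 6 rose, 9 adjusted over the list alone (camera adjusted p = 4.87e-06, and adjusted p = 0.285 with an estimated correlation). Among them were Birc5, encoding survivin (1.00 ± 0.14), Ccnb2, a mitotic cyclin (0.91 ± 0.16), Ube2c (0.90 ± 0.14) and Cdc20 (0.67 ± 0.13), which act in mitotic protein degradation. Of 18 DNA replication genes 3 rose, 10 adjusted over the list alone (camera adjusted p = 0.00014, and adjusted p = 0.262 with an estimated correlation). They were Rrm2, a ribonucleotide reductase subunit (1.08 ± 0.20), the cyclin gene Ccne1 (0.71 ± 0.15) and the helicase component Gins2 (0.68 ± 0.15). Of the 3, 0, 0 and 0 stayed called without wild type 1, 2 and 3 and 3, 1 and 0 without labelled knockout 1, 2 and 3. The mitosis genes that stayed called were 0, 0 and 2 of 6 without wild type 1, 2 and 3 and 6, 3 and 0 without labelled knockout 1, 2 and 3.

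Some feedback targets of Wnt signalling fell, but the list was not called. Notum, Axin2 (-0.84 ± 0.15), a scaffold that limits the pathway, and Tcf7 (-0.85 ± 0.20), a transcription factor of the pathway, made up the 3 of 17 Wnt target genes that fell. The cyclin gene Ccnd1 was at 0.67 ± 0.17 and did not pass. Adjusted over the list alone, 5 fell and 3 rose (camera adjusted p = 0.17). Of 17 intestinal stem cell genes, Axin2 and Tnfrsf19 (-1.46 ± 0.21) fell, 2 also adjusted over the list alone (camera adjusted p = 0.306 for the list). The stem cell receptor gene Lgr5 did not pass at -0.72 ± 0.23. Prom1 went the other way at 1.03 ± 0.34 and did not pass either, and 5 of the 17 fold changes were positive. In the Notch pathway list, the effectors Hey1 (-0.97 ± 0.17) and Heyl (-0.94 ± 0.21) fell, 2 of 11, or 3 adjusted over the list alone (camera adjusted p = 0.0313, and adjusted p = 0.584 with an estimated correlation). The effector Hes1 (0.47 ± 0.25) and Atoh1 (0.69 ± 0.37) had the 2 positive fold changes, and neither passed. Which cells these changes came from was not tested. The call of the Notch list was lost under scaling by library totals (camera adjusted p = 0.0776), without wild type 3 and without labelled knockout 1, where the camera adjusted p was 0.0854. It was also lost without both of these libraries (0.0928) and under library totals without the 20 most abundant genes. Of the 3 Wnt targets, 1, 0 and 1 stayed called without wild type 1, 2 and 3 and 3, 2 and 0 without labelled knockout 1, 2 and 3. Hey1 and Heyl stayed called only without labelled knockout 1, and Axin2 and Tnfrsf19 only without labelled knockout 1 and without labelled knockout 2.

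The lists around ERK signalling itself were not called with all libraries, while single members rose. Of 18 genes of ERK feedback and immediate response, only Etv4, an ETS transcription factor induced by ERK, passed, and it rose, by 1.30 ± 0.20, also adjusted over the list alone (camera adjusted p = 0.33). Etv4 stayed called only without labelled knockout 1 and without labelled knockout 2. The mean of this list, centred over the libraries, was -0.18, -0.042 and -0.025 in wild type 1 to 3 and -0.39, 0.37 and 0.27 in labelled knockout 1 to 3. The list was called higher without labelled knockout 1 (camera adjusted p = 0.0452), with a mean log2 fold change of 0.40 compared with 0.17, and without both libraries with low segment scores (0.0252), with 0.43. The feedback inhibitor Spry1 was at -0.44 ± 0.16, and Ier3 and Phlda1, induced by growth factors, were at 0.61 ± 0.18 and 0.66 ± 0.21, none of which passed. Of 22 cascade components 3 rose, and 3 adjusted over the list alone, among them Map2k2, which encodes the ERK kinase MEK2 (0.90 ± 0.20), and Rps6ka1, a kinase that ERK activates (0.60 ± 0.14). Map2k1 did not pass at 0.51 ± 0.16 (camera adjusted p = 0.63). Among 7 EGF family ligands, Nrg1 (2.46 ± 0.21, limma adjusted p = 0.006) and Ereg (2.72 ± 0.40) rose, 2 also adjusted over the list alone, and Hbegf did not pass at 0.23 ± 0.30 (camera adjusted p = 0.144). The EGF ligand list was called without wild type 3, without labelled knockout 1 and without both (camera adjusted p = 0.00901). Map2k2 and Rps6ka1 stayed called only without labelled knockout 1. Nrg1 and Ereg were 1, 1 and 2 of 2 without wild type 1, 2 and 3 and 2, 2 and 0 without labelled knockout 1, 2 and 3.

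Among other cell types, the B cell and endothelial lists were called lower. Of 10 B and plasma cell genes 6 fell, 8 adjusted over the list alone, with a median log2 fold change of -1.63 (camera adjusted p = 2.88e-05, and adjusted p = 0.373 with an estimated correlation). Fcer2a, the low-affinity IgE receptor (-3.24 ± 0.33), Cd79a, Cd22 (-1.32 ± 0.21) and Cr2 (-3.19 ± 0.56) were among them, Cr2 with mean normalised counts of 18.3 in wild type and 1.33 in the libraries labelled knockout. Of 12 endothelial genes 4 fell, 4 also adjusted over the list alone (camera adjusted p = 0.000466, and adjusted p = 0.285 with an estimated correlation). Among them were Cdh5 (-0.78 ± 0.14), Pecam1 (-0.74 ± 0.14) and Kdr (-0.81 ± 0.15), which encode a junction cadherin, a platelet and endothelial adhesion molecule and a VEGF receptor. In the tuft cell list 1 of 7 members fell, or 4 adjusted over the list alone (camera adjusted p = 0.00809, and adjusted p = 0.587 with an estimated correlation), and Dclk1 did not pass at -1.24 ± 0.43. The smooth muscle list had 1 of 11 lower, Hhip (-1.16 ± 0.25), an antagonist of hedgehog signalling, and 2 adjusted over the list alone (camera adjusted p = 0.0158, and adjusted p = 0.587 with an estimated correlation). Its call was lost without both wild type 3 and labelled knockout 1 (camera adjusted p = 0.141), without wild type 3 alone (0.0645) and without labelled knockout 1 alone, where its mean log2 fold change was -0.30, compared with -0.49 with all libraries. In the interferon response list Ifit3 (-1.40 ± 0.26) and Rtp4 (-0.86 ± 0.15) fell and Mx1 (1.41 ± 0.28) rose. These were 3 of 17, or 4 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.0158, and adjusted p = 0.587 with an estimated correlation). That call was lost without wild type 2, where the camera adjusted p was 0.0962 and the mean was -0.27 compared with -0.45, and without labelled knockout 1. Ifit3, Rtp4 and Mx1 stayed called only without labelled knockout 1, and Hhip only without labelled knockout 1 or 2. Of the 6 B cell genes, 6, 4 and 0 stayed called without labelled knockout 1, 2 and 3. Without a wild type library 3 of them, Fcer2a, Cr2 and Ms4a1, did not pass the filter, and of the other 3, 1, 0 and 1 stayed called without wild type 1, 2 and 3. Fcer2a, Cr2 and Ms4a1 passed the filter only through the wild type libraries, so they could enter the list only as falls. With all libraries the mean log2 fold change of the B cell list was -1.71, and -1.28 over the 7 members besides them. Of the 4 endothelial genes, 0 stayed called without wild type 1, 2 or 3, and 4, 2 and 0 without labelled knockout 1, 2 and 3.

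Lists of absorptive function were not called as a whole. Of 15 brush border hydrolases only Lct passed, and it fell, 1 also adjusted over the list alone. The list leaned the other way, with 10 of 15 fold changes positive and a median of 0.59 (camera adjusted p = 0.261). Of 13 brush border cytoskeleton genes Myo1a, the brush border myosin, rose by 1.24 ± 0.20, 2 adjusted over the list alone (camera adjusted p = 0.23). Of 15 nutrient transporters Slc7a8, an amino acid exchanger, fell by 0.82 ± 0.16 on the log2 scale, 1 adjusted over the list alone (camera adjusted p = 0.691). Of 19 fat absorption genes Dgat1, which completes triglyceride synthesis, rose by 0.77 ± 0.17, 0 adjusted over the list alone (camera adjusted p = 0.416). Lct, Slc7a8 and Dgat1 stayed called only without labelled knockout 1, and Myo1a also without wild type 3 and labelled knockout 2.

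Libraries of each genotype did not form tight groups. Pearson correlations over tested genes ran from 0.933 to 0.988 for the 6 pairs within a genotype and from 0.910 to 0.953 for the 9 pairs between genotypes. Wild type 1 and 2 were at 0.988 and labelled knockout 2 and 3 at 0.980. Component 1 held 46.4% of the variance and separated the genotypes, and component 2, with 32.3%, set wild type 3 and labelled knockout 1 apart from the rest. These are the 2 libraries with the low segment scores. Y-linked Ddx3y had 303, 428 and 0 normalised counts in wild type 1 to 3 and 177, 0 and 0 in labelled knockout 1 to 3. Xist was at 6551, 5924 and 4596 in the 3 libraries without Ddx3y and at 19 or less in the others. Exocrine pancreas transcripts made up 0.403% of the total in wild type 1 and between 0.00516% and 0.0518% in the other 5 libraries.

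**Figure D3:**
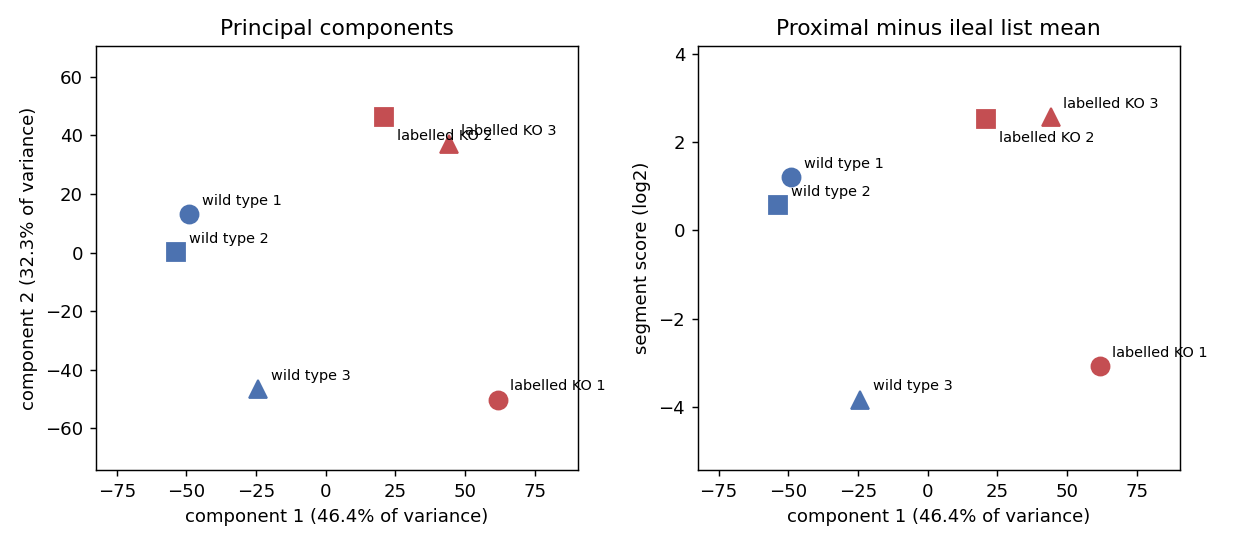
Principal components 1 and 2 of the 6 libraries (left) and component 1 against the segment score in log2 units (right), for wild type (blue) and labelled knockout (red) replicates 1 to 3. Component 1 separates the genotypes, and wild type 3 and labelled knockout 1 lie low on component 2 and have segment scores of -3.82 and -3.07.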

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

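The covariates, the trimmed-mean scaling, the other pseudocounts, limma-voom on values times the estimated factors and leaving out both libraries with low segment scores were chosen after seeing the data. A count model from DESeq2 and the list test on its statistic were not run, since the values are not counts. The 1291 calls became 5338 with limma-voom and sample quality weights, 4315 with the segment score, 459 with sex and 3888 without both libraries with low segment scores. They became 52 at an adjusted p under 0.01 and 716 at a 2-fold minimum, which are stricter by construction. Leaving out 1 library gave 28 to 2998, and these fits have 1 library fewer and drop genes seen in too few libraries. The higher share was 28.7% with limma-voom, 28.3% with limma-voom on values times the estimated factors, 35.5% with quality weights and 27.8% without the 20 most abundant genes, where the median log2 fold changes of all genes were -0.19, -0.19, -0.13 and -0.20. In the other settings, apart from the replicate block given below, the count was 935 to 1555. None of the 1291 changed sign where tested. Where libraries were only left out, no sign could change, since all 1291 had the genotypes apart. Under the other scalings it was largely fixed by the size of the called genes' fold changes. Apart from sex, the cause of these shifts was not tested.

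With the replicate block, a paired fit, 64 genes were called, 85.9% of them higher. Whether the numbers pair the libraries is not known. Deviations of same-numbered libraries correlated at -0.37, 0.30 and -0.16, and not every library correlated best with its own number. Deviations from a genotype mean are tied to each other. A pairing weaker than the other differences between libraries would not show, so pairing was not excluded.

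Of the 17 called lists, 12 were called in all 6 fits that left out 1 library and 5 were not; the number was 0 with an estimated correlation and 17 to 20 in the other camera settings, counting other lists gained. Without both libraries with low segment scores, 4 of the 17 lost their call, namely neutrophil (0.0759), Notch (0.0928), smooth muscle (0.141) and amino acid stress (0.211), and 7 others gained one. With fry, 5 lost it, namely Paneth cell, tuft cell, suckling-type, interferon and smooth muscle. Mapk3 turned negative at -0.0888 with library totals, -0.0893 with limma-voom, -0.21 with quality weights, -0.10 without the 20 most abundant genes, -0.0882 with limma-voom on values times the estimated factors and -0.25 without both libraries with low segment scores, and ran from -0.10 to 0.22 when 1 library was left out. Of lists that were not called, camera's direction turned in these cases, given with the list mean: T cell at 0.0101 without a filter, fatty acid oxidation at -0.16 with sex, and, without both libraries with low segment scores, stem cell at -0.0141, fat absorption at -0.15 and adipose tissue at 0.0195. It also turned for these lists and ileal bile acid genes with 1 library left out, where means ran from -0.46 to -0.0924 for fatty acid oxidation, -0.11 to 0.0937 for adipose tissue, -1.02 to 0.21 for ileal bile acid genes, -0.0349 to 0.37 for T cell, -0.28 to 0.0252 for stem cell and -0.0847 to 0.13 for fat absorption. Some of these fits tested 5 of 6 ileal and 9 of 10 T cell members. Both segment lists were left out under the segment score, which they define. The cause was not tested.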

Other observations

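The tests on Mapk3, both covariates and the lists of the cholesterol hypothesis were chosen after the patterns were seen. The bounds of the covariate and lipid tests were written before their results, but the rule that they must also hold with any 1 library left out, and the test on 7 weaned-type members, came after.

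Among the gene lists not described so far, single members stood out. Xbp1, which drives the unfolded protein response, rose by 0.57 ± 0.13 on the log2 scale, 1 of 14 members over all genes and 1 adjusted over the list alone (camera adjusted p = 0.13). Of 12 p53 targets, the nuclease gene Aen rose by 0.61 ± 0.14 and Trp53inp1, a gene of cell death and autophagy, changed by -1.36 ± 0.22, or 2 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.874). Krt7, a keratin of simple epithelium, rose by 1.44 ± 0.34, 1 of 11 genes of YAP and fetal-type epithelium and 3 adjusted over the list alone (camera adjusted p = 0.274). Adgre1, the macrophage marker F4/80, changed by -0.96 ± 0.22, 1 of 13 macrophage and dendritic genes and 2 adjusted over the list alone (camera adjusted p = 0.254). Gzmb, encoding granzyme B, rose by 2.15 ± 0.46, 1 of 10 T cell genes and 1 adjusted over the list alone (camera adjusted p = 0.883). In the T cell list the mean log2 fold change was positive, at 0.23, and the median negative, at -0.16. Alas2, the haem synthesis enzyme of red cells, rose by 1.58 ± 0.21, 1 of 3 red blood cell genes tested. Of these genes, only Alas2 and Krt7 stayed called without wild type 3, and none without wild type 1, wild type 2 or labelled knockout 3. All stayed called without labelled knockout 1.

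Apart from the list of targeted kinases, no member was called in 11 lists: enteroendocrine cell (camera adjusted p = 0.158), fatty acid oxidation and ketogenesis (0.881), bile acid handling of the ileum (0.691), proximal intestine (0.306), class II antigen presentation (0.144), fibroblast and matrix (0.19), enteric neuron and glia (0.282), exocrine pancreas (0.241), adipose tissue (0.894), mast cell and replication-dependent histones. Of their 105 members tested, 14 had an unadjusted limma p under 0.05 and 3 were called by limma-voom. The last 2 lists had too few members for camera, as had the red blood cell and targeted kinase lists, and the mitochondrially encoded list had no member tested. For adipose tissue camera pointed up while its mean and median were -0.02, and for ERK cascade components the mean was 0.05 and the median -0.005. Adjusted over the list alone, 2 proximal intestine genes passed. Some lists that were not called were called in single settings. Class II antigen presentation and enteroendocrine cell were called lower without wild type 3, without labelled knockout 1 and without both (camera adjusted p = 0.00052 for each without both). Without both, exocrine pancreas and macrophage genes were also called lower and proximal intestine higher, exocrine pancreas also without wild type 3 alone (0.00552) and proximal intestine also without labelled knockout 1 alone. The unfolded protein response was called higher without wild type 3, without labelled knockout 3 (0.00882) and with the segment score. Fabp6, the ileal bile acid binding protein, was at 1947 normalised counts in labelled knockout 1 and at 4 or less in the other 5 libraries.

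The calls between the labelled genotypes were set against structure in the libraries. Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many genes, the real one with 1291, and the highest of the others gave 7, but 10 splits are too few for a share under 0.05. With the segment score as a covariate, the median ratio of the called genes' fold changes was 1.02, and all 1291 stayed called. The score did not separate the genotypes, and the called genes were picked for small spread within them. A ratio near 1 was thus largely fixed, so it does not decide on position along the intestine as a cause. Sex gave a median ratio of 1.01 and a median size of 1.06 compared with 1.07, largely fixed in the same way and undecided as a cause. Only 436 of the 1291 stayed called with sex. Standard errors were 1.08 times as large at the median, and total degrees of freedom were 5.87 compared with 6.99. With 6.99 degrees of freedom, 1050 stayed called, and the fit without sex kept 582 when given 5.87, so the loss of degrees of freedom accounted for most of the lost calls. With the segment score they were 7.34. Genotype and other differences between litters or animals that follow the labels remain open as untested.

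Full totals of Mapk3 in libraries labelled knockout could come from exchanged labels. Against this, with a knockout that removes the transcript, the lowest library for Mapk3 held 59.6% of the highest, so no library under any label lacked it. A deletion that leaves most of the transcript, or one limited to part of the cells, may also give full totals, and the Mapk3 fold of 1.06 cannot be told apart from it, because gene totals hold no exon values. A set of libraries without any deletion was not tested.

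The loss of suckling-type and gain of weaned-type expression could reflect pieces from different segments. With the segment score, both lists were still called with a preset correlation (camera adjusted p = 1.1e-05 for weaned-type and 0.00262 for suckling-type) but not with an estimated correlation (0.434 and 0.507), as without the score. Of single members, 7 of 10 and 7 of 12 were called with the score. How much of either list it accounts for stays open. The mean log2 fold change of the weaned-type list was 2.02 compared with 2.20, a ratio of 0.918, which was 0.793 without labelled knockout 1, under the bound of 0.8. In the 7 members outside the antimicrobial and Paneth cell lists it was 1.22 compared with 1.57, a ratio of 0.778, and the ratio without labelled knockout 1 was 0.466. For the suckling-type list it was -0.91 compared with -1.31, a ratio of 0.697, which ran from 0.554 without wild type 2 to 1.08 without wild type 3. An earlier switch to the weaned state in the libraries labelled knockout remains a hypothesis.

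A hypothesis for the cholesterol synthesis genes is that the cells held less sterol, which would lower the targets of the sterol receptor LXR. The 10 LXR targets had a mean log2 fold change of -0.48, with 2 lower (Abcg1 at -1.60 ± 0.31 and Mylip at -0.96 ± 0.18) and 0 higher, but the list missed the threshold (camera adjusted p = 0.0659 over 2 lists, and adjusted p = 0.247 with an estimated correlation). The mean of the list is in the direction the hypothesis needs. However, 3 of the 10 fold changes were positive, among them Srebf1 at 0.50 ± 0.39, and the list does not settle it. A rise of lipid synthesis as a whole may be an alternative: the 13 fatty acid synthesis genes had a mean of 0.19 with 1 higher, Scd2 at 1.28 ± 0.24 (camera adjusted p = 0.151), which leaves that open too.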
